A study of Mus musculus with 12 samples.

How the data were processed

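Total RNA of sorted mouse T cells was hybridised to 12 Illumina mouse arrays, 1 per sample, in 4 groups of 3: Treg and Teff, each from Blimp1-sufficient (Ctrl) and Blimp1-deficient (CKO) donors aged 8 to 12 weeks. RNA was purified with Qiagen RNeasy columns and turned into biotin-labelled cRNA with the Ambion MessageAmp kit, per the labels. The labels do not say that replicates of a group come from separate animals, so p-values measure the spread between these samples. The deposited values are log2 intensities per probe. The submitters' processing notes name GenomeStudio and limma 3.30.11. The background correction, the normalization between arrays and any probe filter are not given in the sources used here. The log2 scale of the deposited values was read from their range, and the arrays have nearly equal quantiles, with medians from 4.66 to 4.68, so they were used as they are. Raw intensities were not analysed here. The number of arrays limits the precision.

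The deposited values covered 31641 probes. Those with a single gene symbol (28197) were used, and 5 with several symbols and 3439 with none were set aside, the latter tested once separately. A probe was kept when it lay above the median of its array on at least 3 of the 12 arrays, which left 19396 probes, and each gene was represented by the kept probe with the highest mean over all arrays. This gave 12119 genes, of which 3764 had several kept probes. Among the named genes and list members, 20 differences past the threshold had other probes of the gene, 36 in all, and 5 of these, all of Foxp3, had the opposite sign.

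Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings), with 1 mean per group and all 12 arrays in the fit, which gave 2.51 prior and 10.5 total degrees of freedom. The comparisons were CKO against Ctrl in Treg and in Teff, Treg against Teff in Ctrl and in CKO, and the interaction, that is the genotype difference in Treg minus that in Teff. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. All tests were two-sided. Other packages were statmod 1.5.0 and data.table (version 1.17.8).

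Gene lists, 27 in number with 378 of 499 members tested, covered T cell programmes, general processes and markers of other cell types. Each was tested with camera at a preset correlation of 0.01 between genes, adjusted over the 27 lists of a comparison, and again with an estimated correlation. Members were counted past the threshold over all genes and adjusted over the list alone. The lists described are those that passed and a few others that bear on helper lineages. Markers of neutrophils and of basophils and mast cells were listed only after the arrays had been seen.

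Named genes followed a rule. Prdm1 and Foxp3 were given in every group. For the genotype comparisons and for Treg against Teff in Ctrl the 10 largest rises and falls among genes past the threshold with no overlap between groups were taken, and directions with fewer than 5 were filled to 5 by the smallest unadjusted p. For Treg against Teff in CKO and the interaction 5 per direction were taken. Up to 4 members per described list were added, and clone names were left out. Il10 beside the Treg and Teff comparisons, Bcl6 and other genes repeated from another comparison were named after their values were seen. The lists, this rule, the design and the alternatives not marked otherwise were fixed before the data were examined.

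Whether replicate numbers pair the arrays was checked by correlating, across genes, the residuals of same-numbered arrays of the groups compared. These correlations were 0.519 to 0.589 for CKO and Ctrl in Treg and 0.348 to 0.737 in Teff, and each array correlated best with its own number in 3 of 3 pairs. Between Treg and Teff they were −0.266 to 0.265 in Ctrl and 0.0413 to 0.325 in CKO. Values with pairs are therefore given beside the genotype results, from a fit with the replicate number within each cell type as a fixed term, which was chosen after seeing the data.

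The pipeline was tested on simulated data with 50 changed genes at each size among 12119. Without pairs it recovered 66% at a log2 fold change of 1, 84% at 2, 92% at 3 and 98% at 4, with 2 false calls. With pairs it recovered 70%, 96%, 98% and 98%, with 19 false calls. For every simulated gene, CKO and Ctrl arrays of the same number and cell type shared part of their deviation. The simulation held many more changed genes than passed between the genotypes in these data. That loosens the Benjamini-Hochberg cutoff, so these shares can overstate the recovery here.

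The alternatives were quantile normalization or median centring, no filter or the 75th percentile, the mean of a gene's probes or every probe, eBayes with trend and robust settings, array weights, the replicate number as a fixed or random block, only the arrays of the groups compared, and leaving out each array. Those chosen after seeing the data were the pairs, the array set as a block or each array set alone, leaving out both Teff arrays numbered 2, leaving out 3 Teff arrays with granulocyte genes, and the Treg signature without Il10. The array sets are 6 arrays with a higher and 6 with a lower lower quartile, in which the genotypes are balanced. The cell types are not balanced. Each genotype has 1 Treg and 2 Teff arrays in the higher set, and 2 Treg and 1 Teff arrays in the lower. Treg against Teff is therefore partly confounded with the array set. Between the sets 1062 of the 12119 genes passed by limma with the groups in the fit. The sets were cut from these same values, at a gap of 0.00577 between lower quartiles. They part the arrays as the first principal component does, at 7.08 or less in the higher set and 16.64 or more in the lower. Basophil and neutrophil genes lead that component. The set is thus not known to be a technical batch, and a fit with it as a block may also take up that signal.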

Results

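Transcripts were measured on 12 Illumina mouse arrays, 3 for each of 4 populations of sorted CD4 T cells. Naive T cells of C57BL/6 mice that carried a green fluorescent Foxp3 reporter, and either had Blimp1 (arrays labelled Ctrl) or lacked it (arrays labelled CKO), were mixed in equal numbers and injected into RAG1-/- mice, which make no T or B cells of their own. Blimp1, encoded by Prdm1, is a transcriptional regulator of effector and terminally differentiated lymphocytes. After 6 to 8 weeks the progeny of both donors were separated by an allotype marker and by the reporter. Foxp3-positive cells are called Treg here (regulatory T cells, labelled pTreg by the submitters), and Foxp3-negative cells Teff (effector T cells). Both donors' cells therefore shared the same hosts. RNA came from cells of the spleen, the mesenteric nodes and the lamina propria of the large bowel, combined and restimulated for 4 h with PMA and ionomycin, which trigger cytokine transcription. The deposited values are on a log2 scale, and the array medians lay between 4.66 and 4.68. Correlations between arrays ran from 0.943 to 0.988, and no pair of arrays was identical. The number of arrays, 3 per group, limits the precision of every value that follows. Errors of group means are SD with n = 3, and errors of log2 fold changes are SE.

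Prdm1, the targeted gene, had a higher signal in the arrays labelled CKO, not a lower one. In Treg the log2 value of probe ILMN_2597923 was 5.77 ± 0.50 (SD, n = 3) in Ctrl and 9.04 ± 0.52 in CKO, a log2 fold change of 3.27 ± 0.38 (limma, adjusted p = 0.00953). In Teff it was 4.92 ± 0.41 in Ctrl and 8.26 ± 0.64 in CKO, a log2 fold change of 3.34 ± 0.38 (adjusted p = 0.0235). The CKO array was the higher in 6 of 6 same-numbered pairs, and the lowest CKO array lay 2.39 above the highest Ctrl array in Treg and 2.45 above it in Teff. A second Prdm1 probe, ILMN_2744650, was at or below 4.56 on every array, under every array median. Where either probe lies relative to the deleted part of the gene is not given in the sources used here, so the Prdm1 signal does not check the genotype labels. Directions between genotypes are therefore given for the arrays labelled CKO against those labelled Ctrl. The Treg call was lost without the array CKO Treg 1 (adjusted p = 0.0870). The Teff call was lost in 10 of the 12 fits that leave out 1 array, with adjusted p from 0.0522 to 0.169, and in 13 of its 26 alternatives in all.

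Foxp3, the lineage factor on which the cells were sorted, separated the sorted populations on its brightest probe, where no genotype difference passed. Its log2 value on probe ILMN_1225330 was 8.02 ± 0.84 (SD, n = 3) in Ctrl Treg and 8.05 ± 0.67 in CKO Treg, against 4.58 ± 0.16 in Ctrl Teff and 4.64 ± 0.19 in CKO Teff. The genotype difference was 0.03 in Treg (95% interval −0.86 to 0.92) and 0.06 in Teff (95% interval −0.83 to 0.95). Its sign was negative with the mean of the gene's probes in Treg (−0.04) and with array weights in Teff (−0.02). It also turned without CKO Treg 1 (−0.35), Ctrl Treg 2 (−0.07) or Ctrl Treg 3 (−0.34) in Treg, and without Ctrl Teff 2 (−0.02) or CKO Teff 3 (−0.05) in Teff. A dimmer Foxp3 probe, ILMN_1251126, was lower in the CKO array of each Treg pair (−0.83, −0.57 and −0.26) and higher in that of each Teff pair (1.79, 1.60 and 0.31), with its highest group mean in CKO Teff (6.41 ± 1.15). With every probe tested alone these differences had an unadjusted p of 0.277 and 0.0273 and an adjusted p of 1.00 each. That probe did not pass between Treg and Teff (adjusted p = 0.639 in Ctrl and 0.585 in CKO). Probes ILMN_2635132 and ILMN_2917180 did not pass either, and their differences were negative (−0.24 and −0.08 in Ctrl, −0.08 and −0.15 in CKO). The statement therefore rests on the brightest probe alone. With the mean of the gene's probes, Foxp3 did not pass between Treg and Teff (adjusted p = 0.0949 in Ctrl and 0.419 in CKO).

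**Figure D1:**
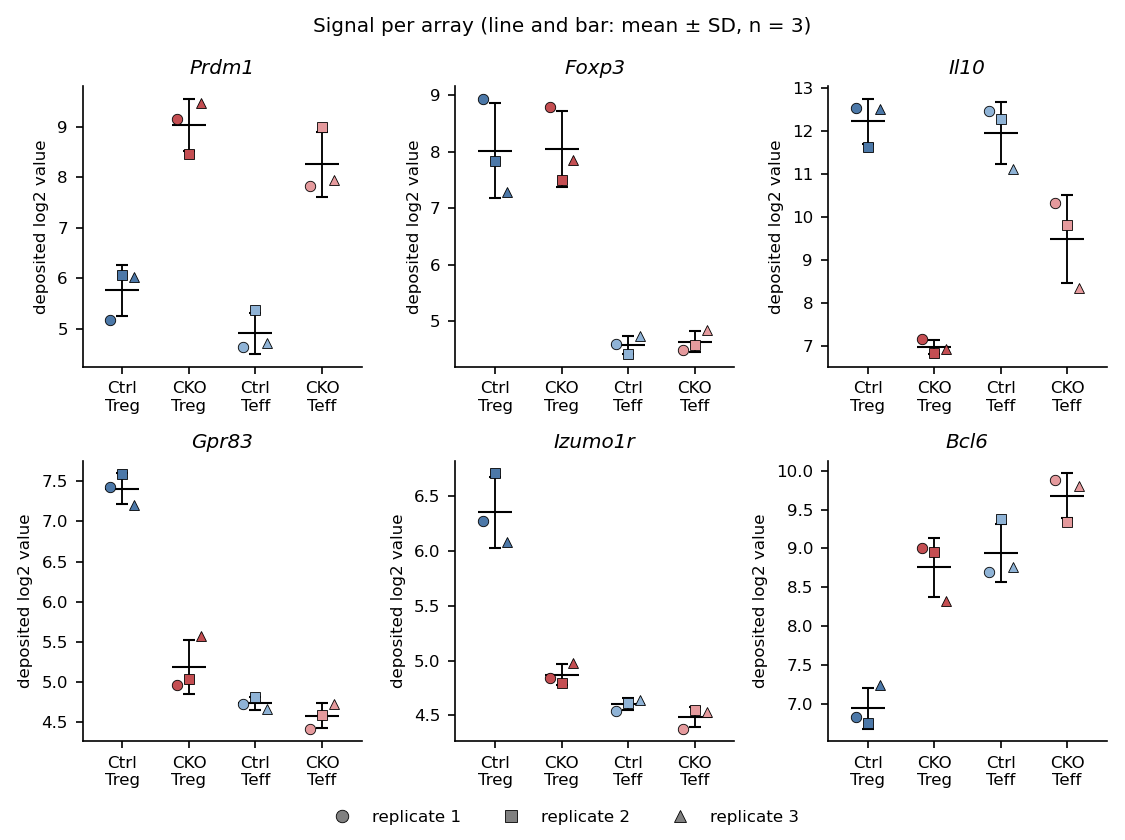
Deposited log2 values of 6 genes on each of the 12 arrays, by group on the horizontal axis. Symbols give the replicate number, and the line and bar give the mean ± SD of n = 3 arrays. Prdm1 is higher in both CKO groups, Foxp3 separates Treg from Teff on its brightest probe, and Il10 drops from 12.22 in Ctrl Treg to 6.98 in CKO Treg.

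The first comparison asked which transcripts of Treg that arose from naive precursors differ between the arrays labelled CKO and those labelled Ctrl. Il10, which encodes the anti-inflammatory cytokine interleukin 10, fell by 5.24 ± 0.49 on the log2 scale in the Treg arrays labelled CKO, from 12.22 ± 0.52 (SD, n = 3) to 6.98 ± 0.16 (adjusted p = 0.00241). Gpr83, an orphan receptor enriched in Treg (log2 fold change −2.22 ± 0.17, adjusted p = 0.000547), and Izumo1r, also known as folate receptor 4 (−1.48 ± 0.15, adjusted p = 0.00385), fell as well. Bcl6, the repressor that directs follicular helper cells and whose expression opposes that of Blimp1, rose by 1.82 ± 0.25 (adjusted p = 0.0222). Slc2a6, a hexose transporter, rose by 2.80 ± 0.35, Hif1a, the oxygen-sensing factor that induces glycolytic genes, by 1.23 ± 0.16, and Pgam1, a glycolytic enzyme, by 0.87 ± 0.11.

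Of the 12119 genes tested in Treg, 12 passed the threshold, 5 higher and 7 lower in CKO, and 9 of them differed at least 2-fold. At an unadjusted p under 0.05 there were 646. The remaining falls were Ncmap (−2.86 ± 0.30), Ky (−1.63 ± 0.12), Trp53i11 (−0.96 ± 0.14) and Pde4d (−0.88 ± 0.12), the last a phosphodiesterase that degrades cyclic AMP. The CKO and Ctrl values did not overlap for any of the 12 genes, nor for 12.3% of all genes tested. Chance gives 10% for independent arrays, which does not hold here, since same-numbered CKO and Ctrl arrays correlated. With the same-numbered Treg arrays treated as pairs, an alternative chosen after seeing the data, 264 genes passed, 107 higher and 157 lower, and all 12 were among them. That larger count fell to 30, 58 and 57 without the Treg pair numbered 1, 2 and 3. Il10, Ncmap, Gpr83, Ky and Izumo1r stayed past the threshold whichever array was left out, and Izumo1r lost its call only with the mean of its probes (adjusted p = 0.176). The count was 5 without CKO Treg 1, 6 without CKO Treg 2 and 8 without Ctrl Treg 1, and Slc2a6, Bcl6, Hif1a, Pgam1, Trp53i11 and Pde4d each lost their call in at least 3 of the 12 such fits, with adjusted p up to 0.226.

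Among the lists fixed beforehand, the Treg signature shifted furthest between the genotypes in Treg. Of its 19 tested genes 16 were lower in CKO, with a median log2 fold change of −0.62 (camera, adjusted p = 6.35e-15, and adjusted p = 0.0416 with an estimated correlation). Il10, Gpr83 and Izumo1r passed over all genes, and 7 passed when adjusted over the list alone. Tnfrsf18, which encodes the costimulatory receptor GITR, was at −1.22 ± 0.20 (adjusted p = 0.0795, 0.0127 with pairs, and 0.00206 to 0.370 over its alternatives). The list's median was −0.61 when Il10 was taken out. With pairs and an estimated correlation the adjusted p was 0.178. The 15 effector Treg genes were lower as a list (median −0.28, 13 negative, adjusted p = 0.00872), but only Il10 passed over all genes or over the list alone, and Icos stood at −0.60 ± 0.34 and Itgae at −0.87 ± 0.53. That call was lost with adjusted p = 0.436 with an estimated correlation, and also without Ctrl Treg 2 (adjusted p = 0.0576) or CKO Treg 3 (adjusted p = 0.0736). The effector Treg list was not tested again without Il10. Il10 and Itgae are also in the Treg signature, so the lists are not independent.

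**Figure D2:**
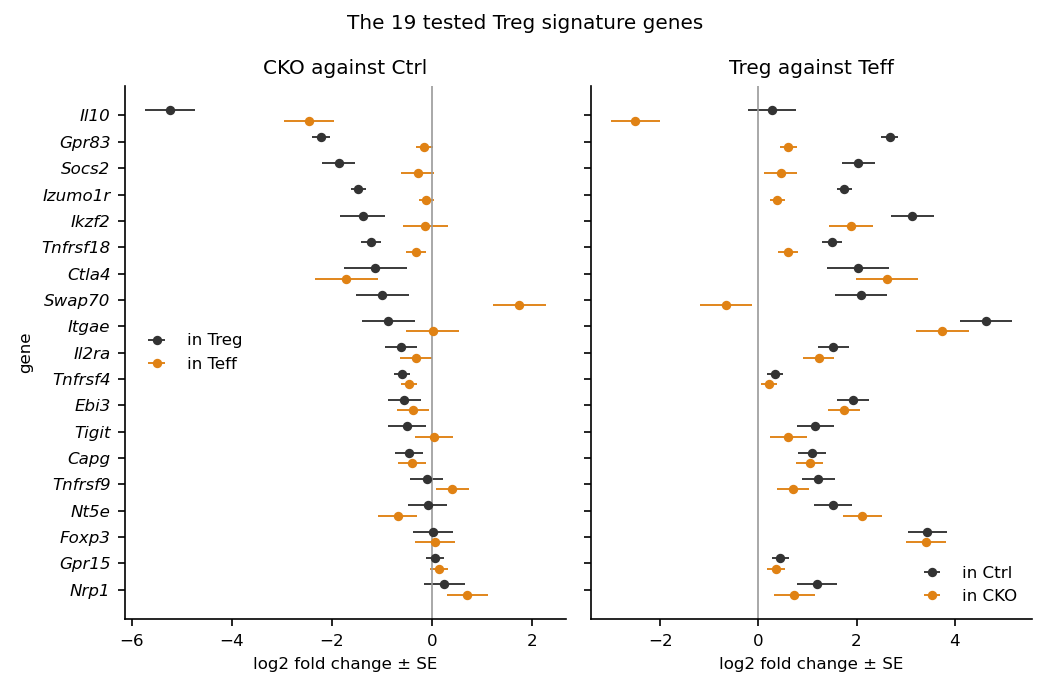
Log2 fold changes with SE of the 19 tested Treg signature genes, ordered by the genotype difference in Treg. The left panel compares CKO with Ctrl within Treg and within Teff, and the right panel compares Treg with Teff within each genotype. In Treg 16 of the 19 genes are lower in CKO, and all 19 are higher in Treg than in Teff among Ctrl arrays.

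The 14 glycolysis genes were higher in CKO Treg as a list (median 0.24, 11 positive, adjusted p = 0.00271, and adjusted p = 0.318 with an estimated correlation). Pgam1 passed over all genes. Adjusted over the list alone, Pgam1 was higher and the glucose transporter gene Slc2a3 lower (−1.25 ± 0.28, adjusted p = 0.212 over all genes and 0.0110 with pairs, 0.0110 to 0.615 over its alternatives), so the members did not all go 1 way. Pfkl, a phosphofructokinase subunit, was at 1.15 ± 0.43 (adjusted p = 0.736, 0.00584 with pairs, and 0.00584 to 1.00 over its alternatives). The 14 apoptosis and survival genes were lower (median −0.24, 12 negative, adjusted p = 0.00389, and adjusted p = 0.197 with an estimated correlation). By limma 0 of them passed over all genes or adjusted over the list alone, and 4 had an unadjusted p under 0.05. Its members with the smallest p included Bbc3, a pro-apoptotic BH3 protein (−0.66 ± 0.20, unadjusted p = 0.00686), and Cdkn1a, a cell cycle inhibitor (−0.89 ± 0.31). The 16 TGF-beta and retinoic acid response genes were lower (median −0.29, 12 negative, adjusted p = 0.00940, and adjusted p = 0.647 with an estimated correlation), with 0 passing by limma over all genes or adjusted over the list alone, 3 at an unadjusted p under 0.05, and Tgfbr2 at −0.51 ± 0.20. That call was lost without Ctrl Treg 1 (adjusted p = 0.129) or CKO Treg 3 (adjusted p = 0.101).

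Helper lineage genes gave no shift as lists in Treg. The Tfh programme (11 genes, median 0.02) missed the threshold (adjusted p = 0.0587), with Bcl6 past it over all genes and 3 higher when adjusted over the list alone, among them Pou2af1 at 2.13 ± 0.51. For the 18 Th17 genes the median was −0.08, the mean 0.09 and the tested direction up (adjusted p = 0.802). Hif1a passed over all genes, and 3 were higher when adjusted over the list alone, with Il17f at 1.89 ± 0.49 and the chemokine receptor gene Ccr6 at 2.47 ± 0.71. For the 20 T helper cytokine genes the median was −0.09, the mean −0.15 and the tested direction up (adjusted p = 0.802). Il10 passed over all genes. Adjusted over that list alone, Il17f, Lta (1.28 ± 0.33) and Tnfsf11, which encodes RANKL (1.07 ± 0.32), were higher and Il10 lower. With pairs, Ccr6, Pou2af1, Lta and Tnfsf11 passed over all genes, with adjusted p between 0.0115 and 0.0217, and Il17f did not (0.0619). Over their alternatives the adjusted p of these 5 genes reached 0.743 to 0.978. With pairs the interferon response (adjusted p = 0.00327), naive and central memory (0.0279) and early activation lists (0.0121) were also lower in CKO Treg, and their values were 0.370, 0.571 and 0.571 with an estimated correlation. Marker genes of neutrophils, listed after seeing the data, were lower in the CKO array of each Treg pair. The mean of 18 of them was 6.46, 5.42 and 6.78 on CKO Treg 1, 2 and 3 and 7.33, 5.61 and 7.32 on Ctrl Treg 1, 2 and 3, and this difference was not tested.

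The second comparison put the same question to Teff. Apart from Prdm1, only Cx3cl1, which encodes the chemokine fractalkine, passed the threshold, rising by 1.11 ± 0.13 from 4.56 ± 0.02 (SD, n = 3) to 5.67 ± 0.23 (adjusted p = 0.0235). Its Ctrl Teff mean lay under every array median, so the rise starts from a signal near background. Il10 was lower in the Teff arrays labelled CKO as well, at 9.49 ± 1.02 against 11.95 ± 0.72, a log2 fold change of −2.46 ± 0.49 that missed the threshold (adjusted p = 0.676) and passed it with pairs (0.00307, with 0.00307 to 1.00 over its alternatives). It was lower in 3 of 3 pairs. Among genes that missed the threshold, the smallest p among higher genes belonged to Slc2a6 (2.34 ± 0.35, adjusted p = 0.144), Tnfsf4, which encodes OX40 ligand (1.34 ± 0.20, adjusted p = 0.144), and Synpo (2.53 ± 0.52). Among lower genes they belonged to Trib2 (−1.37 ± 0.26), Tmem154 (−1.27 ± 0.24), Grap2, an adaptor of T cell receptor signalling (−1.30 ± 0.26), and Xpc, a DNA damage sensor (−0.93 ± 0.20), besides Il10.

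In Teff 2 genes were higher and 0 lower by limma, with 505 genes at an unadjusted p under 0.05. The genotypes did not overlap for 6.77% of all genes tested. Chance gives 10% for independent arrays, but same-numbered arrays correlated, so the share cannot be read as below chance. Pairing the arrays raised the count to 12, 5 higher and 7 lower, among them Slc2a6, Tnfsf4, Tmem154, Grap2, Xpc and Cd74, with adjusted p between 0.00821 and 0.0497 that reached 1.00 under other alternatives. That count was 4, 34 and 123 without the Teff pair numbered 1, 2 and 3, and 6 without the Treg pair numbered 1. Without CKO Teff 3 the unpaired count was 52, without CKO Treg 2 it was 3, and without any other array it was 0, when Prdm1 and Cx3cl1 had adjusted p up to 0.169. Without both Teff arrays numbered 2 it was also 0, with 483 genes at an unadjusted p under 0.05.

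Lists that shifted between genotypes in Teff were those of other lineages and of interferon. The 9 CD8 and NK cell markers were higher in CKO as a list (median 1.00, 8 positive, adjusted p = 0.000186, and adjusted p = 0.504 with an estimated correlation). By limma 0 of its genes passed over all genes, 3 had an unadjusted p under 0.05, and 2 passed when adjusted over the list alone, the NK receptor genes Klra7 (4.98 ± 0.51 in Ctrl and 8.28 ± 2.53 in CKO, SD, n = 3) and Klre1 (log2 fold change 2.54 ± 0.81). Klre1 also spread widely within CKO Teff, with an SD of 2.06. The mean of the list was 7.26, 8.64 and 6.06 on CKO Teff 1, 2 and 3, against 6.14, 6.21 and 5.98 on the Ctrl Teff arrays. Without Ctrl Teff 2, CKO Teff 1 and CKO Teff 2, an alternative chosen after seeing the data that leaves 1 CKO Teff array, the median was 0.02 and the call was lost (adjusted p = 0.884). The 15 myeloid markers were higher (median 0.69, 14 positive, adjusted p = 0.000356, and adjusted p = 0.713 with an estimated correlation), with 0 passing by limma over all genes or adjusted over the list alone and 3 at an unadjusted p under 0.05. The MHC class II genes H2-Aa (2.10 ± 0.62), H2-Ab1 (2.24 ± 0.68) and Cd74 (1.85 ± 0.66) had the smallest p. The call was lost without CKO Teff 2 (adjusted p = 0.0504) or Ctrl Teff 3 (adjusted p = 0.277).

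The 17 interferon response genes (median 0.41, 13 positive, adjusted p = 0.0370, and adjusted p = 0.774 with an estimated correlation) and the 13 cytotoxic granule genes (median 0.10, 9 positive, adjusted p = 0.00245, and adjusted p = 0.504 with an estimated correlation) were also higher in CKO Teff as lists. By limma 0 of their genes passed over all genes or adjusted over the list alone, and at an unadjusted p under 0.05 there were 0 and 3. Examples were Rsad2, an antiviral protein (1.54 ± 0.87), Ctsw, a cathepsin of cytotoxic cells (0.75 ± 0.25), and Lamp1, a lysosomal membrane protein (0.52 ± 0.15). The interferon call was lost without Ctrl Teff 1 (0.677), Ctrl Teff 3 (0.724) or CKO Teff 2 (0.610), and without the last its median was −0.07. With no probe filter the interferon call was lost as well. The cytotoxic call was lost without CKO Teff 2 (0.148), Ctrl Teff 3 (0.121) or both Teff arrays numbered 2 (0.170). Without Ctrl Teff 2, CKO Teff 1 and CKO Teff 2 its median turned to −0.19 (0.971), and the interferon call was lost (0.237). With pairs the chemokine receptor and homing list was higher (0.0283), and the effector Treg (0.0283) and cell cycle lists (0.000158) were lower, and all were at 0.50 with an estimated correlation. Marker genes of granulocytes varied between the Teff arrays as well. The mean of the 18 neutrophil markers was 7.04, 7.56 and 6.11 on CKO Teff 1, 2 and 3 and 6.37, 8.14 and 5.60 on Ctrl Teff 1, 2 and 3. The mean of 10 basophil and mast cell markers was 6.67, 6.11 and 4.95 on the CKO Teff arrays and between 4.80 and 5.10 on the other 9 arrays.

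**Figure D3:**
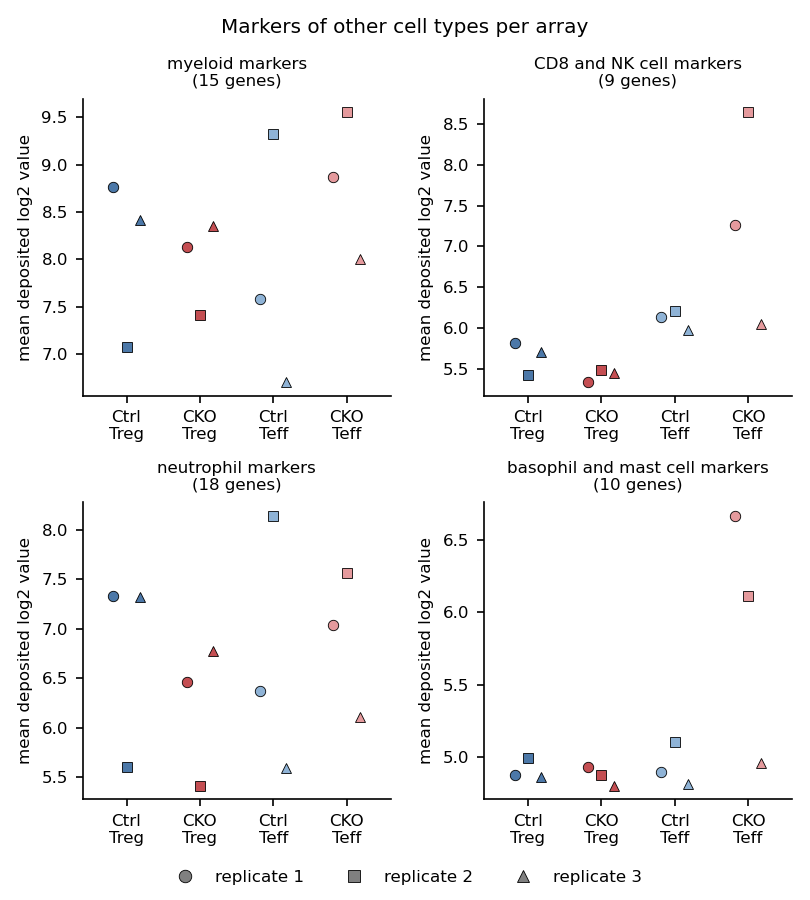
Mean deposited log2 value, per array, of the tested markers of myeloid cells (15 genes), CD8 T and NK cells (9 genes), neutrophils (18 genes) and basophils and mast cells (10 genes). Symbols give the replicate number. Basophil and mast cell markers stand at 6.67 and 6.11 on CKO Teff 1 and 2 and at 5.10 or less on the other arrays.

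The genotype difference was then compared between the cell types. Gpr83 and Ky were the genes whose difference in Treg departed from that in Teff. The difference of the log2 fold changes was −2.07 ± 0.24 for Gpr83 and −1.54 ± 0.17 for Ky (limma interaction, adjusted p = 0.0308 for each). In Teff both lay near the array median in either genotype, Gpr83 at 4.73 ± 0.08 (SD, n = 3) and 4.57 ± 0.16, so there was little signal there to lose. Ncmap (−2.79 ± 0.43), Izumo1r (−1.36 ± 0.21) and Cx3cl1 (−1.20 ± 0.18) missed the threshold (adjusted p = 0.150 for each). Il10, lower in CKO in both cell types, had an interaction of −2.78 ± 0.70 that also missed it, and Hif1a led the genes of positive sign (1.20 ± 0.22, adjusted p = 0.519), followed by Cep85 (0.87 ± 0.18), Cdon (1.44 ± 0.31), Mast4 (1.73 ± 0.43) and Slc25a47 (0.83 ± 0.21).

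By limma the interaction had 2 genes lower and 0 higher, with 422 at an unadjusted p under 0.05. With pairs it had 5, including Ncmap (adjusted p = 0.00776), Il10 (0.0124) and Ky (0.0259), while Gpr83 was at 0.0556. Over their alternatives the adjusted p of Ncmap, Il10, Ky and Gpr83 reached 0.998 or more. Those 5 became 0, 7 and 119 without the Teff pair numbered 1, 2 and 3, and 0, 4 and 2 without the corresponding Treg pair. The unpaired count was 22 without CKO Teff 3, 3 without Ctrl Treg 3, 1 without CKO Treg 3 and 0 without any other array, where Gpr83 and Ky stood between 0.0720 and 0.160. The 19 Treg signature genes (median −0.51, adjusted p = 1.76e-08, and 0.206 with an estimated correlation) had 1 gene past the threshold and 6 when adjusted over the list alone. The 9 CD8 and NK cell markers (median −1.33, adjusted p = 0.000376, and 0.443 with an estimated correlation), the 17 interferon response genes (median −0.87, adjusted p = 0.00441, and 0.672 with an estimated correlation) and the 15 myeloid markers (median −1.15, adjusted p = 0.00441, and 0.585 with an estimated correlation) had 0 by limma either way, with 2, 1 and 0 genes at an unadjusted p under 0.05. Examples were Klra7 (−3.75 ± 1.34), the interferon-induced GTPase gene Igtp (−1.39 ± 0.60) and Fcer1g, a signalling chain of myeloid and NK receptors (−2.64 ± 1.77). The interferon call was lost without Ctrl Treg 1 (0.0858), Ctrl Teff 1 (0.113), CKO Teff 2 (0.487) or Ctrl Teff 3 (0.266), and the myeloid call without Ctrl Treg 1 (0.0858), CKO Teff 2 (0.0915) or Ctrl Teff 3 (0.286). The CD8 and NK call was lost without Ctrl Teff 2, CKO Teff 1 and CKO Teff 2 together (0.527). With pairs 12 lists passed for the interaction, and 0 of the 27 did by camera with pairs and an estimated correlation. Prdm1 was the 1 gene called in both cell types, where independent lists would share 0.000825 genes. It is the gene targeted in both, so that expectation is no measure of a shared response. With pairs 7 genes were shared. Without each array in turn the shared count was 0 in 10 of the 12 fits and 2 without CKO Teff 3. Of the 12 genes called in Treg, 11 had the same sign in Teff. Across all genes tested the log2 fold changes of Treg and Teff correlated with r = 0.119 (Spearman 0.055), where genes are not independent replicates.

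The third comparison described what sets Treg apart from Teff in the cells of the arrays labelled Ctrl. Itgae, the integrin chain CD103 that retains lymphocytes in epithelia, rose by 4.64 ± 0.53 in Ctrl Treg over Ctrl Teff (adjusted p = 0.00326), and Foxp3 by 3.44 ± 0.40 (adjusted p = 0.00330). Ikzf2, which encodes the transcription factor Helios, rose by 3.14 ± 0.45, Gpr83 by 2.68 ± 0.17, Izumo1r by 1.75 ± 0.15 and Tnfrsf18 by 1.50 ± 0.20. The inflammatory cytokine genes Il17f (−4.39 ± 0.49) and Il17a (−3.63 ± 0.37) fell, from log2 values of 12.44 ± 1.00 (SD, n = 3) and 11.45 ± 0.35 in Ctrl Teff to 8.05 ± 0.34 and 7.82 ± 0.92 in Ctrl Treg. Il10, in contrast, was at 12.22 ± 0.52 in Ctrl Treg and 11.95 ± 0.72 in Ctrl Teff.

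Further genes with large rises were Syp (3.77 ± 0.39), Pdzk1ip1 (3.62 ± 0.58), Ncmap (3.37 ± 0.30), Ephx1, an epoxide hydrolase (2.86 ± 0.38), Rragd, a GTPase that signals amino acids to mTORC1 (2.81 ± 0.47), and Grb7 (2.60 ± 0.34). Those with large falls were Esm1 (−3.08 ± 0.36), Crtam (−2.99 ± 0.56), the surface receptor gene Cd160 (−2.96 ± 0.39), Jaml (−2.94 ± 0.47), Mmp10 (−2.74 ± 0.49), Serpinb6b (−2.70 ± 0.41), the glutamate transporter gene Slc17a6 (−2.61 ± 0.41) and Pdzk1 (−2.61 ± 0.29). Of the 12119 genes tested 123 passed, 73 higher and 50 lower in Treg, with 1260 at an unadjusted p under 0.05. With each array centred on its median the split was 52 higher and 54 lower. Treg and Teff are not balanced over the array sets. With the set as a block, an alternative chosen after seeing the data, 178 passed, 120 of the 123 among them. Values of Treg and Teff did not overlap for any of the 123, nor for 14.3% of all genes tested, where chance gives 10%. The count was 51, 44, 49 and 70 without Ctrl Treg 1, Ctrl Treg 2, Ctrl Teff 1 and Ctrl Teff 2. Without these or the other arrays in turn, Itgae, Foxp3, Syp, Ncmap, Gpr83, Izumo1r, Tnfrsf18, Il17f, Il17a, Esm1, Cd160 and Pdzk1 all stayed past the threshold, as did Ephx1 and Grb7. Ikzf2 was lost without Ctrl Treg 2 (adjusted p = 0.0524). Pdzk1ip1, Rragd, Crtam, Jaml, Mmp10, Serpinb6b, Slc17a6, Tnfsf11, Il2 and Stat4 lost their call in 2 to 5 of the 12 fits, in each case without Ctrl Treg 2 among them, with adjusted p up to 0.160.

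As lists, all 19 Treg signature genes were higher in Ctrl Treg (median 1.53, adjusted p = 1.76e-26, and adjusted p = 0.00641 with an estimated correlation), 8 over all genes and 17 when adjusted over the list alone. Of 20 T helper cytokine genes 16 were lower (median −1.34, adjusted p = 8.89e-13, and adjusted p = 0.0599 with an estimated correlation), 4 over all genes and 12 over the list alone. They included Tnfsf11 (−2.18 ± 0.32) and Il2, the growth factor that Treg consume (−1.33 ± 0.23). The 14 Th1 genes were lower (median −0.62, adjusted p = 1.15e-05, and 0.194 with an estimated correlation), with Stat4, a signal transducer of interleukin 12, passing over all genes (−1.86 ± 0.30) and 2 genes over the list alone, Ccl5 at −2.54 ± 0.54. The 18 Th17 genes gave a median of −0.01 and a mean of −0.58 (adjusted p = 0.0362, and 0.194 with an estimated correlation), with Il17a and Il17f past the threshold over all genes and 5 lower over the list alone, among them the chemokine gene Ccl20 (−3.02 ± 0.65). That call was lost in 11 of its 24 alternatives. Among them were median centring, array weights, the replicate number as a fixed block and the array set as a block. It was lost without Ctrl Treg 1 (0.0522), Ctrl Treg 3 (0.132), Ctrl Teff 2 (0.205) or CKO Teff 3 (0.0524). Leaving out both Teff arrays numbered 2, or Ctrl Teff 2, CKO Teff 1 and CKO Teff 2 together, lost it too. Its median was 0.20 without Ctrl Teff 2 and 0.07 without Ctrl Treg 3. The 13 cytotoxic granule genes were lower (median −0.64, adjusted p = 0.00178, and 0.264 with an estimated correlation), with Serpinb6b past the threshold over all genes, and over the list alone 5 lower, Klrd1 (−2.44 ± 0.55) among them, and 1 higher. The 15 effector Treg genes (median 0.38, adjusted p = 1.65e-05, and 0.172 with an estimated correlation) and the 15 chemokine receptor and homing genes (median 0.49, adjusted p = 0.00587, and 0.488 with an estimated correlation) were higher. Itgae passed over all genes in each, and over each list alone 5 and 4 were higher, among them the chemokine receptor gene Ccr8 (3.34 ± 0.71), with 1 homing gene lower. The homing call was lost without Ctrl Treg 2 (0.0663) or Ctrl Teff 3 (0.0818).

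**Figure D4:**
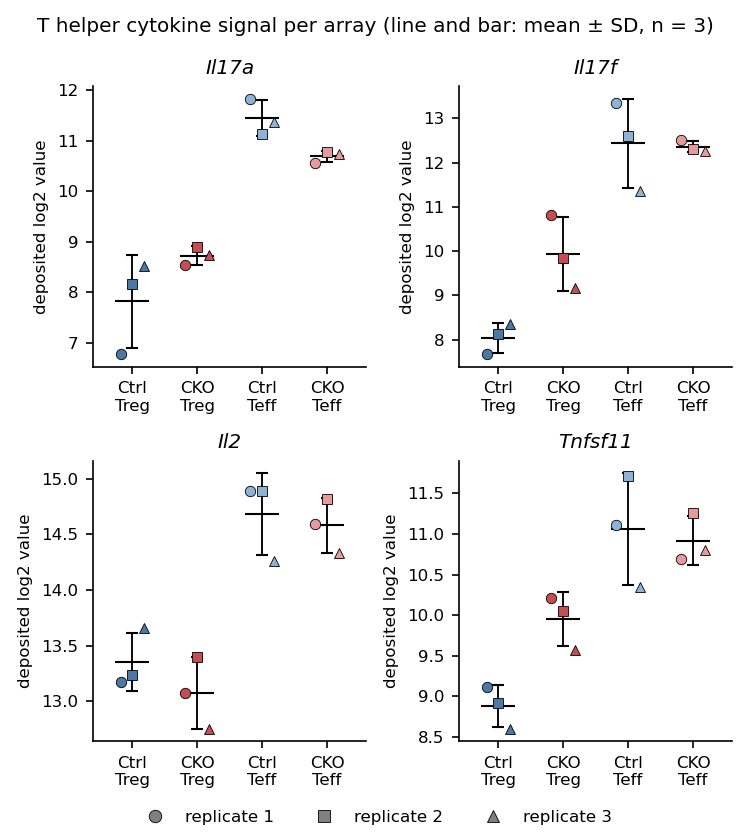
Deposited log2 values of 4 T helper cytokine genes on each of the 12 arrays, by group on the horizontal axis. Symbols give the replicate number, and the line and bar give the mean ± SD of n = 3 arrays. All 3 Ctrl Treg arrays lie below all 3 Ctrl Teff arrays for each gene.

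The last comparison repeated this in the cells of the arrays labelled CKO. Foxp3 (3.41 ± 0.40), Itgae (3.75 ± 0.53) and Syp (3.31 ± 0.39) again rose in CKO Treg over CKO Teff, together with Tmem154 (1.91 ± 0.24) and Gzf1 (1.87 ± 0.30). Klrd1, which encodes the NK receptor CD94 (−3.77 ± 0.55), the chemokine gene Ccl5 (−3.45 ± 0.54), Jaml (−3.52 ± 0.47), Serpinb6b (−3.27 ± 0.41), Esm1 (−3.24 ± 0.36) and Il2 (−1.51 ± 0.23) fell. Il10 was at 6.98 ± 0.16 in CKO Treg and 9.49 ± 1.02 in CKO Teff (SD, n = 3), a log2 fold change of −2.51 ± 0.49 that missed the threshold (adjusted p = 0.0623). Il17a (−1.97 ± 0.37, adjusted p = 0.0532) and Il17f (−2.42 ± 0.49, adjusted p = 0.0670) missed it as well.

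In these cells 43 genes passed, 21 higher and 22 lower in Treg, with 1305 at an unadjusted p under 0.05, and the groups did not overlap for 13.7% of all genes tested, where chance gives 10%. The count was 259 without CKO Teff 3, 16 without CKO Treg 1, 27 without Ctrl Teff 1, 20 and 23 without CKO Teff 1 and CKO Teff 2, 23 without CKO Treg 2 and 23 without CKO Treg 3, and it was 3 without Ctrl Teff 2, CKO Teff 1 and CKO Teff 2 together. Of the named genes, Foxp3, Syp, Serpinb6b and Esm1 stayed past the threshold whichever array was left out, and Itgae, Tmem154, Gzf1, Klrd1, Jaml, Ccl5 and Il2 lost their call in 1 to 6 of the 12 fits, in each case without CKO Treg 1 among them (adjusted p up to 0.119). The 20 T helper cytokine genes were lower (median −1.82, adjusted p = 1.50e-15, and adjusted p = 0.0636 with an estimated correlation), Il2 over all genes and 14 over the list alone. Among the 14 were Il4, Il5 and Il13, which lead the first principal component together with basophil and neutrophil genes such as Prss34. The 19 Treg signature genes were higher (median 0.71, 17 positive, adjusted p = 6.67e-10, and 0.0744 with an estimated correlation), 2 over all genes and 11 over the list alone, where 1 was lower. The 14 Th1 genes (median −0.85, adjusted p = 2.59e-08, and 0.0805 with an estimated correlation), the 13 cytotoxic granule genes (median −1.27, adjusted p = 7.17e-07, and 0.0805 with an estimated correlation) and the 9 CD8 and NK cell markers (median −2.02, adjusted p = 1.33e-07, and 0.115 with an estimated correlation) were lower. Over all genes 1, 2 and 1 of them were lower. Over the lists alone 7, 8 and 4 were lower, and 1 cytotoxic granule gene was higher. The means of the CD8 and NK cell markers on CKO Teff 1 and 2 given above enter these 3 lists, in which Klre1 (log2 fold change −3.33 ± 0.81) and Klra7 (4.98 ± 0.23 in CKO Treg and 8.28 ± 2.53 in CKO Teff, SD, n = 3) missed the threshold over all genes. In all, 16 lists passed in this comparison and 0 of the 27 did with an estimated correlation, by camera.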

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

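The splits of the arrays were planned, except the regroupings that part all 6 pairs, and those and the tests of the 3 patterns that follow them (Prdm1, the Treg falls and the myeloid markers) were chosen only after the result was seen. The interaction marked the following results as different between Treg and Teff. Gpr83 differed by −2.07 and Ky by −1.54 on the log2 scale, and the median difference was −0.51 for the Treg signature, −1.33 for the CD8 and NK cell markers, −0.87 for the interferon response genes and −1.15 for the myeloid markers. With an estimated correlation all 4 list calls were lost, with adjusted p = 0.206, 0.443, 0.672 and 0.585 in that order.

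For CKO against Ctrl in Treg the real split gave 12 genes and the highest of the other splits 0, with 1 of 10 splits as large. For Treg against Teff the real split gave 123 genes in Ctrl and 43 in CKO, the highest other 0 in each, with 1 of 10 splits as large. For CKO against Ctrl in Teff 2 of 10 splits gave at least the real count of 2, and the highest other gave 467. In each of these comparisons the 10 splits are too few for a share under 0.05. The split with 467 sets Ctrl Teff 1, Ctrl Teff 3 and CKO Teff 3 against Ctrl Teff 2, CKO Teff 1 and CKO Teff 2, and it points to a structure of the samples. Among the 4 splits of the Teff arrays that part all 3 pairs, the highest other gave 0, and the split with 467 leaves the pairs numbered 2 and 3 together. For the interaction 10 of 100 regroupings gave at least the real count of 2, and the highest other gave 190, so chance is not excluded. Among the 32 regroupings that part all 6 pairs, 8 gave at least 2 and the highest other gave 14, and each of the 8 keeps the Treg arrays as labelled.

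Prdm1 was higher in the arrays labelled CKO in both cell types, although CKO marks loss of its product. A swap of single arrays is argued against, since every CKO array lay above every Ctrl array of its cell type, with a smaller gap of 2.39. Labels exchanged for all 12 arrays cannot be told apart from the labels given, since Prdm1 was higher in the CKO array in 6 of 6 pairs. The rise of Bcl6 (1.82) and fall of Il10 (−5.24) in CKO Treg run the way known for loss of Blimp1, but are outcomes of the comparison and were not chosen beforehand to mark the genotype. A probe outside the deleted part of the gene cannot be told either, since the second probe reached only 4.56 and lay below every array median, and loss of a repression of Prdm1 by its own product may also raise the signal and is an untested hypothesis.

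Gpr83, Izumo1r and Il10 fell in CKO Treg. Foxp3-negative cells in the CKO Treg sort are argued against as the whole cause, since the lower 95% bound of the Foxp3 difference on its brightest probe was −0.86 and the smallest of the 3 falls was −1.48. On the dimmer probe, which did not separate Treg from Teff, that bound was −1.62 and decides nothing. A dependence of these genes on Blimp1 in Treg may account for the falls and stays open as a hypothesis, with the direction resting on the genotype labels.

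The myeloid markers were higher in CKO Teff, with a median difference over the 15 genes of 1.02, −0.25 and 1.33 in the pairs numbered 1, 2 and 3 and a mean difference of 1.29, 0.23 and 1.30. Both arrays of each pair, in Treg as in Teff, are in 1 array set, so by the design a shift common to a set does not enter the genotype differences and was not tested. Carried-over granulocytes and basophils, which a sort on CD4 should remove, are a candidate source that these data do not settle, with the neutrophil gene S100a8 at 12.88 ± 1.67 (SD, n = 3) in Ctrl Teff and 13.41 ± 0.69 in CKO Teff. The median difference of 28 neutrophil, basophil and mast cell markers, 2 of them also in the myeloid list, was 0.34 with 21 positive. It was 0.52, −0.14 and 0.11 in these pairs. The myeloid median was negative in the same pair, so the negative value there does not speak against carry-over. Taken alone, basophil and mast cell markers had a higher mean in the CKO array of each Teff pair. The neutrophil mean was higher in the pairs numbered 1 and 3 and lower in pair 2. Only the 2 shared genes of the 15 myeloid markers were in the test of 28 markers, and carry-over of other myeloid cells was not tested. An effect of the genotype was not tested apart from these.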

How the results depend on the processing

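Settings with pairs, with the array sets and without 2 or 3 Teff arrays, and the Treg signature without Il10, were chosen only after the result was seen. Counts are given for CKO against Ctrl in Treg, CKO against Ctrl in Teff, Treg against Teff in Ctrl, Treg against Teff in CKO, the interaction and the genes shared by the genotype comparisons. Over the named genes and comparisons, 108 in all, 106 kept direction and side of the threshold with quantile normalization and 106 with median centring, 107 without a filter and 102 with the mean of a gene's probes. Fewer did without both Teff arrays numbered 2 (91) or without 3 Teff arrays (86), and 66 of 94 with only the arrays compared, where 27 lost their call. Of 38 list calls, 37 held with quantile normalization, 35 with median centring, 34 without a filter, 31 with the 75th percentile filter and 2 with an estimated correlation. With the array set as a block 30 held and 8 were lost. Without both Teff arrays numbered 2, 28 held and 1 turned, and without the 3 Teff arrays 23 held and 5 turned. The Treg signature without Il10 held in 4 of 4 comparisons. With pairs 41 of 59 named genotype and interaction results kept their side of the threshold, 17 passed newly and 1 (Gpr83 in the interaction) was lost, and 13 of 13 list calls held. The cause of the changes that follow was not tested, except where fewer genes, fewer arrays or fewer degrees of freedom are part of the setting.

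The 75th percentile filter, which tests fewer genes, gave 1 gene in Teff, 82 between Treg and Teff in CKO and 0 for the interaction (limma, 170 at an unadjusted p under 0.05). Trend and robust settings gave 86 in CKO, 4 for the interaction and 2 shared. Array weights gave 34 in Treg, 247 in Ctrl and 245 in CKO. The replicate number as a fixed block gave 44 in Treg, 333 in Ctrl, 250 in CKO and 1 for the interaction, and as a random block 30, 266 and 175 in Treg, Ctrl and CKO. Only the arrays compared, with fewer degrees of freedom, gave 25 in Treg, 0 in Teff (317 at an unadjusted p under 0.05), 29 in Ctrl and 4 in CKO. Pairs gave 264 in Treg, 12 in Teff, 5 for the interaction and 7 shared. The array set as a block, over which Treg and Teff are not balanced, gave 25 in Treg, 178 in Ctrl and 66 in CKO. Of the 43 genes called in CKO without it, 40 were among the 66. Either array set alone leaves 1 array in each Treg group of the higher set and in each Teff group of the lower. That is too few for a count of genes to decide anything, so none is read from these fits. Without both Teff arrays numbered 2 the counts were 29 in Treg, 0 in Teff (483), 0 for the interaction (489) and 0 shared. Without Ctrl Teff 2, CKO Teff 1 and CKO Teff 2, where the lone CKO Teff array is assumed to vary like the other groups, they were 35 in Treg, 0 in Teff (529), 3 in CKO, 0 for the interaction (496) and 0 shared.

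Leaving out each array in turn gave 5 to 17 genes in Treg, 0 to 52 in Teff, 44 to 163 in Ctrl, 16 to 259 in CKO, 0 to 22 for the interaction and 0 to 2 shared. The Foxp3 genotype difference ranged from −0.35 to 0.49 in Treg and from −0.050 to 0.13 in Teff, was −0.045 in Treg with the mean of its probes, and was −0.024 in Teff with array weights. The interferon median ranged from −0.071 to 1.03 for the genotypes in Teff and from −0.57 to −0.0052 between Treg and Teff in CKO, where it was −0.0052 without both Teff arrays numbered 2, and the tested direction turned. Without the 3 Teff arrays the cytotoxic granule median in Teff was −0.19, and between Treg and Teff in CKO the medians were 0.38 for early activation, −0.42 for cell cycle, 0.13 for erythrocyte markers and 0.27 for interferon response genes. Not run were the scale log2 with another offset, since the values were already log2, the random block for lists, only the arrays compared for the interaction and for lists, and every probe for the shared genes. Probes near the array medians limit what can be seen of genes that are off in a group.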

Other observations

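The tests with pairs, those without 2 or 3 Teff arrays and the marker lists of granulocytes named here were chosen only after the result was seen. Early activation genes, induced within hours of stimulation, were lower in Treg than in Teff as a list. In Ctrl 14 of 20 were lower (median −0.43, adjusted p = 0.00354, and adjusted p = 0.687 with an estimated correlation), and Dusp2, a phosphatase of MAP kinases, fell by 1.26. Over the list alone 5 were lower and 1 higher. The call was lost without Ctrl Teff 2 (0.333), Ctrl Treg 3 (0.0866) or both Teff arrays numbered 2 (0.384). It was also lost without Ctrl Teff 2, CKO Teff 1 and CKO Teff 2, and with the array set as a block. In CKO 17 of 20 were lower (median −0.78, adjusted p = 4.34e-05, and 0.472 with an estimated correlation), 1 over all genes and 4 over the list alone, but without Ctrl Teff 2, CKO Teff 1 and CKO Teff 2 the median turned to 0.38 (adjusted p = 0.463). Cholesterol synthesis genes were higher in Ctrl Treg (12 genes, median 0.31, 11 positive, adjusted p = 0.0362, and 0.687 with an estimated correlation), with 0 by limma over all genes or over the list alone and 1 at an unadjusted p under 0.05. That call was lost in 9 of its 24 alternatives. Among them were the 75th percentile filter, the mean of a gene's probes and the array set as a block. It was lost without Ctrl Teff 1 (0.0759), Ctrl Teff 2 (0.237) or Ctrl Treg 3 (0.289). Leaving out both Teff arrays numbered 2, or Ctrl Teff 2, CKO Teff 1 and CKO Teff 2, lost it too.

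In CKO further lists separated Treg from Teff. Effector Treg genes (median 0.44, adjusted p = 0.00211, and 0.247 with an estimated correlation) and glycolysis genes (median 0.35, 11 of 14 positive, adjusted p = 0.00956, and 0.279 with an estimated correlation) were higher in Treg. Genes of the unfolded protein response and secretion were lower (17 of 18, median −0.28, adjusted p = 0.00739, and 0.365 with an estimated correlation). For apoptosis and survival genes the tested direction was down (median −0.11, adjusted p = 0.00739, and 0.128 with an estimated correlation), and 6 passed over the list alone. Only 7 of these 14 genes were negative, so the members did not all go 1 way. All 20 cell cycle genes were higher (median 0.44, adjusted p = 0.0347, and 0.663 with an estimated correlation). The costimulatory TNF receptors and ligands (median −0.32, adjusted p = 0.0304, and 0.466 with an estimated correlation), myeloid markers (median −0.90, adjusted p = 0.0215, and 0.520 with an estimated correlation), 3 erythrocyte markers (median −0.62, adjusted p = 0.0403, and 0.384 with an estimated correlation) and interferon response genes (median −0.35, adjusted p = 0.0485, and 0.663 with an estimated correlation) were lower, and the chemokine receptor and homing genes higher (median 0.36, adjusted p = 0.0496, and 0.520 with an estimated correlation). Over all genes 1 effector Treg gene and 1 homing gene were higher, 1 costimulatory gene was lower and by limma 0 genes of the other lists passed. Over the list alone 4 effector Treg, 3 glycolysis, 4 homing and 2 costimulatory genes were higher and 1, 1, 1 and 4 lower. In the lists with 0 either way, 1 gene of the unfolded protein response, 2 myeloid, 1 erythrocyte, 0 cell cycle and 0 interferon genes had an unadjusted p under 0.05. The effector Treg and unfolded protein response calls were lost without CKO Teff 3 (0.106 and 0.0779). The cell cycle, costimulatory, myeloid, erythrocyte, interferon and homing calls were lost in 3, 4, 3, 5, 8 and 7 of the 12 fits that leave out 1 array, in that order, with adjusted p from 0.0506 to 0.868. Over all 24 alternatives they were lost with the direction kept in 7, 9, 7, 11, 13 and 13, and the direction turned in 1, 0, 0, 1, 3 and 0. Without Ctrl Teff 2, CKO Teff 1 and CKO Teff 2 the median turned to −0.42 for cell cycle (0.229), 0.13 for erythrocyte markers (0.722) and 0.27 for interferon response genes (0.0748). The glycolysis, apoptosis, costimulatory and myeloid calls were lost there too. The glycolysis call was also lost with the 75th percentile filter and without both Teff arrays numbered 2.

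The first principal component held 39.5% of the variance and the second 15.8%. On the first, Ctrl Teff 2 stood at −43.43, CKO Teff 1 at −31.11 and CKO Teff 2 at −50.29, and Ctrl Teff 3 at 22.39 and CKO Teff 3 at 19.58. Its leading genes included the basophil protease genes Prss34 and Mcpt8, the neutrophil genes Camp, Ltf and Mpo, and Il4, Il5 and Il13. The mean of 13 leading genes of granulocytes was 11.48, 11.38 and 7.18 on CKO Teff 1, 2 and 3 and 8.08, 10.04 and 5.99 on Ctrl Teff 1, 2 and 3. It was 7.78, 5.80 and 8.26 on CKO Treg 1, 2 and 3 and 9.10, 5.69 and 8.70 on Ctrl Treg 1, 2 and 3.

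Of 7 genes that fell in CKO Treg, 5 were higher in Ctrl Treg than in Ctrl Teff (Ncmap, Gpr83, Izumo1r, Trp53i11 and Ky), and of 5 that rose, Bcl6 was lower. Both comparisons use the Ctrl Treg arrays, with opposite sign, so overlap of this kind can arise without a change. Across genes, which are not independent replicates, their log2 fold changes correlated with r = −0.338, against −0.501 in 100 simulations with no difference and shared controls. Probes without a gene symbol, 1817 of them, were tested alone and gave 0, 0, 1, 7 and 0 past the threshold by limma for the genotypes in Treg and Teff, Treg against Teff in Ctrl and in CKO, and the interaction, with 84, 75, 190, 164 and 56 at an unadjusted p under 0.05.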
